A study of Homo sapiens with 12 samples.

How the data were processed

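The series holds 64 two-colour spotted arrays of immune genes, each hybridised with RNA of HT-29 cells treated for 3 h and of untreated HT-29 cells. Per the labels, RNA had an integrity number over 9.0, was isolated with TRIzol and RNeasy columns, reverse transcribed with SuperScript III and labelled with Cy3 or Cy5. The deposited scanner output of each array gives spot and local background intensity in both channels, per the file headers quantified with QuantArray and not background subtracted. The series table of the authors holds 1 ratio of treated over untreated cells per gene name and treatment, taken as log2. It was made by them with R 2.13.0 and limma, with steps that are not stated. The dye of the treated RNA was read from the image names in the headers, which matched the file names on every array: it was Cy5 on 33 arrays and Cy3 on 31. No array was left out.

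Each array holds 3168 spots. Of 1352 gene names 1240 are current symbols, 84 were updated from older ones and 28 had no match and kept the name on the array; 186 spots are empty and 228 carry no name. Most names have 2 spots (1329) and 23 have 4 or 6 spots of more than 1 probe, so 1377 probes were tested. Where a gene had several probes, the one with the highest mean intensity stood for it. In 11 gene comparisons at least 1 probe was called and another not, and in 1 both were called with opposite signs (SI after B. infantis, log2 changes 0.52 and -0.3). In none were all probes of a gene called in 1 direction. After E. coli the highest and lowest log2 changes were 1.58 and -0.33 for B2M and 1.5 and -0.27 for POLR2A. Calls of genes with 1 probe had no such check. Spots marked as ignored by the quantification were left out (0 to 196 per array, median 8.5). A gene lay above the empty spots on an array where it exceeded percentile 95 of that array's empty spots in either channel, and 1108 of 1352 genes did so on a share of at least 0.5 of the arrays. A gene above them on no array of a treatment in 1 of the RNAs has only a bound there, taken from normalised log2 values of each channel against the dimmest detected probe per array. Brightness of 65000 or more was taken as saturated, which held for 0 to 26 probes per array.

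Background was corrected with normexp (offset 50) and dyes were balanced by loess over each array with empty and control spots given no weight, in limma 3.58.1 under R 4.3.3. Spots were averaged to probes. A single linear model over all arrays had 1 coefficient per treatment, with sign by dye orientation, and 1 dye column, and tests used the moderated statistic of eBayes with Benjamini-Hochberg adjustment over all probes at a threshold of 0.05. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The median log2 change of all genes per treatment lay between -0.021 and 0.015, and with median centring, printing-block loess or scaling the farthest from 0 was -0.034. The dye effect passed the test in 716 genes, with an SD of 0.193 over genes.

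The comparisons were each of 12 treatments against untreated cells, the means of the 3 Gram-negative bacteria, the 3 bifidobacteria and the 4 lactobacilli against untreated cells, and 6 contrasts between treatments. In contrasts n counts the arrays of all treatments they involve. Treatments were taken as fixed, so the SE and p of means and contrasts cover the spread between arrays and not that between strains. There were 24 gene lists: NF-kB subunits and feedback inhibitors, chemokines, neutrophil-attracting chemokines, cytokines of innate and epithelial cells, T helper cytokines, TLR and IL-1 receptor signalling, NOD-like receptors and inflammasome, MAP kinase cascade, AP-1 and immediate early genes, type I interferon response, JAK-STAT and SOCS, TNF receptor family and death receptors, BCL2 family and caspases, antimicrobial and mucosal defence, mucins with trefoil factors and tight junctions, adhesion molecules, heat shock and chaperones, oxidative stress and hypoxia, EGF receptor ligands and growth factors, TGF-beta and SMAD signalling, cell cycle, antigen presentation, leukocyte markers and housekeeping genes. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the lists within a comparison. The fry test of limma was run beside them. The groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

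Named genes came from a rule. Among genes past the test and changed in 1 direction on a share of at least 0.75 of a treatment's arrays, it takes the 10 highest and 5 lowest log2 changes (20 and 10 for the Gram-negative mean). It adds up to 4 called members of each gene list and 12 fixed genes: CXCL8, CCL20, NFKBIA, TNFAIP3, ATF3, JUN, TLR2, TLR3, TLR4, MYD88, IRF1 and HSPA1A. Between treatments it takes the 5 highest and 5 lowest. The text prints a subset of these, chosen after the values were seen; 259 called gene values were followed through the alternatives. ATF3 was not on the array. Apart from that choice, 2 further genes of the rule are not reported here.

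The self-test put simulated arrays with known changes through the same model and tests. Their noise was drawn from a normal distribution with the fitted spread of each probe, independently between arrays and genes. Correlation within slides or between genes and single noisy arrays were not simulated, so the shares of false calls below leave these out. Of spiked probes, 73.1% with a log2 change of 0.5 were called in the E. coli design (n = 4), 80.6% in that of L. farciminis (n = 6) and 94% in that of B. infantis (n = 8); with a change of 1 it was 97%, 98.5% and 98.5%, and with 2 it was 100% in each. False calls made up 2.7%, 3.1% and 2% of calls in the same order. A moved chemokine list was called (adjusted p = 3.95e-54), and 0 of 22 lists that share no gene with it were.

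Alternatives were other thresholds (adjusted p with at least 1.3-fold, and the threshold in the design text of the series, p under 0.05 unadjusted with at least 1.3-fold), no background correction or plain subtraction, median centring in place of loess, Aquantile between arrays, no dye column, a dye effect per slide, each treatment fitted alone, array weights, the slide as a random block, probes above the median intensity, near-duplicate file names averaged, and each array left out in turn. Added after the data were seen were loess within printing blocks (span 0.4), scale normalisation, the imaging session as a block, background from the empty spots, only genes above the empty spots, and leaving out the noisiest array. The arrays lay on 44 slides and in 18 imaging sessions (arrays whose images shared a folder). Of these, 12 slides and 4 sessions held more than 1 treatment. The dye effect per slide gave an own term only to slides that held both dye orientations, and all other slides shared 1 term. The slide and session blocks act on the ratio of Cy5 over Cy3. Where a block holds both orientations, a shift of treated over untreated cells changes sign within it and is not captured.

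As a check for exchanged dyes, arrays of 1 orientation and different treatments were correlated across genes before orientation was removed: the lowest r was -0.2, and 0 of 932 pairs lay under -0.3. The median correlation between arrays of a treatment was 0.58 for E. coli, 0.56 for S. Typhimurium, 0.18 for S. Enteritidis, 0.33 for LPS, 0.28 for B. infantis, 0.19 for B. bifidum, 0.16 for L. helveticus, 0.01 for L. plantarum, 0.05 for L. farciminis, 0.06 for L. rhamnosus, -0.04 for B. longum and 0.39 for S. boulardii. Across genes, the log2 changes computed here had r between 0.92 and 0.992 with the series table of the authors. Slopes ran from 0.679 to 0.885 in the same direction. Its scale was taken as log2, which these slopes do not settle, and whether its columns were centred is unknown. Its column medians were -0.00748 for E. coli, 0.0105 for S. Typhimurium, 0.00263 for S. Enteritidis, -0.00583 for LPS, 0.0133 for B. infantis, -0.00371 for B. bifidum, -0.00276 for L. helveticus, -0.00324 for L. plantarum, 0.00435 for L. farciminis, -0.000932 for L. rhamnosus, 0.0021 for B. longum and -0.000912 for S. boulardii. Genes are not independent replicates. The number of arrays limits the precision. Random regroupings turned the signs of arrays, or exchanged treatment labels in contrasts, up to 100 times, with 235 missing values filled by fitted ones and the fitted dye effect subtracted beforehand, so their real counts differ from those of the report, most for LPS against Gram-negative bacteria (56 against 44).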

Results

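HT-29 cells, a human colon adenocarcinoma line used as a model of the gut epithelium, were exposed for 3 h to 1 of 12 microbial stimuli. The question, from the title and design of the series, was how immune signalling genes of the epithelial cell respond to commensal, pathogenic and probiotic microorganisms. The Gram-negative bacteria Escherichia coli ATCC 25922, Salmonella Typhimurium ATCC 14028 and an isolate of Salmonella Enteritidis were added at 5 bacteria per cell, and lipopolysaccharide (LPS, a component of their outer membrane) at 1 µg/mL. The bifidobacteria, the lactobacilli and the yeast Saccharomyces boulardii I-1079 were added at 100 per cell. Each two-colour array carried RNA of treated and of untreated cells in the Cy5 and Cy3 dyes, in both orientations for every treatment. E. coli, both Salmonella, LPS, Bifidobacterium longum R0175 and S. boulardii had 4 arrays each. Lactobacillus helveticus R0052, L. plantarum 299v, L. farciminis R1127 and L. rhamnosus R0011 had 6 each, and B. infantis R0033 and B. bifidum R0071 had 8 each, which made 64 arrays. The design text of the series calls them biological replicates, so n below is the number of arrays. The arrays measured 1352 gene names. The median spot brightness of an array lay between 237.6 and 952.3 in Cy5 and between 146.2 and 893.9 in Cy3, and 634 to 1294 genes lay above the empty spots (median 1062). The number of arrays limits the precision: the median standard error of a log2 change was 0.13 with 4 arrays, 0.106 to 0.107 with 6 and 0.0918 with 8. Changes are given as the fold and the log2 change of treated over untreated cells ± its standard error (SE), and a gene rose or fell where its Benjamini-Hochberg adjusted p, over all probes, was under 0.05. Some members of gene lists, given without a value, lie outside the rule for named genes and were chosen after their values were seen.

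After S. Typhimurium 208 genes passed the test, after E. coli 163, after B. infantis 156 and after S. boulardii 80. After B. bifidum 55 passed, after L. helveticus 50, after S. Enteritidis 38 and after LPS 11. After B. longum 6 passed, after L. plantarum 3 and after L. farciminis 1. After L. rhamnosus 0 genes passed the limma test, with 30 at an unadjusted p under 0.05.

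**Figure D1:**
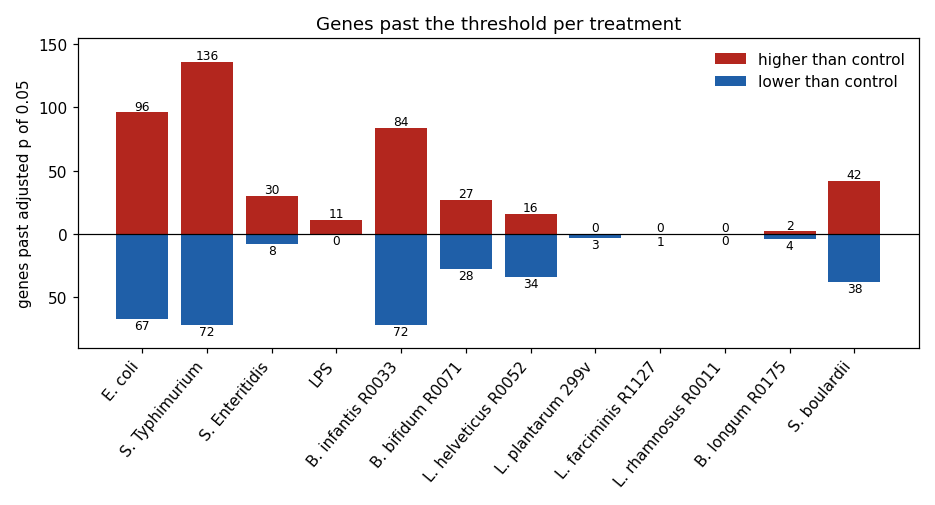
Number of genes with an adjusted p under 0.05 after each of the 12 treatments (genes higher in treated cells above 0, genes lower below 0, counts printed on the bars). S. Typhimurium had 136 higher and 72 lower, and L. rhamnosus R0011 had 0.

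The comparison of E. coli with untreated cells asks what a commensal type of Gram-negative bacterium changes. Chemokine genes had the largest changes among the genes named by the rule. CXCL8 rose 14.2-fold (3.83 ± 0.285), n = 4, adjusted p = 1.54e-16, and was higher on 4 of 4 arrays; it encodes interleukin-8, which attracts neutrophils. The neutrophil attractants CXCL2 and CXCL1 rose 13.6-fold (3.77 ± 0.214) and 11.9-fold (3.57 ± 0.2), and CCL20, an attractant of dendritic cells and lymphocytes, rose 9.25-fold (3.21 ± 0.279). The NF-kB inhibitor NFKBIA rose 5.18-fold (2.37 ± 0.114), the phosphatase DUSP1 6.92-fold (2.79 ± 0.371) and the AP-1 subunit JUN 5.48-fold (2.455 ± 0.325). CSF2, which encodes the growth factor GM-CSF, rose 5.66-fold (2.50 ± 0.209), and the adhesion molecule ICAM1 2.62-fold (1.39 ± 0.139). Among lower genes, ID1, a target of BMP signalling, fell 2.36-fold (-1.24 ± 0.144), the death receptor adaptor FADD 1.87-fold (-0.90 ± 0.104) and the cell cycle inhibitor CDKN1B 1.93-fold (-0.95 ± 0.138).

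Of 163 genes past the test after E. coli, 96 were higher and 67 lower. No gene with several probes had all of them called after E. coli. Of 6 measured neutrophil-attracting chemokines 5 rose, CXCL1, CXCL2, CXCL3, CXCL6 and CXCL8, and 0 fell, 5 and 0 adjusted over the list alone (camera adjusted p = 2.62e-16, and 3.22e-06 with an estimated correlation). Of 17 measured NF-kB subunits and feedback inhibitors 8 rose, 1 fell, IKBKG, and 8 did not pass (8 and 1 adjusted over the list alone; adjusted p = 5.27e-06, and adjusted p = 0.023 with an estimated correlation). Of 25 cytokine genes 8 rose and 0 fell (8 and 2 adjusted over the list alone; adjusted p = 0.00156, and adjusted p = 0.103 with an estimated correlation). Of 14 AP-1 and immediate early genes 5 rose, DUSP1, DUSP4, FOS, JUN and JUND, and DUSP6 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00166, and adjusted p = 0.462 with an estimated correlation). Among all 40 chemokines 7 rose and 1 fell, CCL8, with a mean log2 change of 0.43 and a median of -0.01, which differ in sign (7 and 1 adjusted over the list alone; adjusted p = 0.0205, and adjusted p = 0.222 with an estimated correlation). Without replicate 2 of E. coli the count was 101 and without replicate 1 it was 106; fitted on its 4 arrays alone it was 28, where FADD and CDKN1B did not pass (adjusted p = 0.0931 and 0.0932). With median centring in place of loess 176 genes were higher and 39 lower, and with the slide or the imaging session as a block 210 or 191 genes passed.

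After S. Typhimurium, a pathogen that invades epithelial cells, the same question was asked. CXCL1 rose 22.8-fold (4.51 ± 0.2), n = 4, adjusted p = 1.29e-26, higher on 4 of 4 arrays, and CXCL8 rose 22.7-fold (4.51 ± 0.285). CCL20 rose 18.3-fold (4.19 ± 0.279), CSF2 11.6-fold (3.54 ± 0.209) and CSF1, the macrophage growth factor, 9.9-fold (3.31 ± 0.218). TNFAIP3, which encodes the NF-kB inhibitor A20, rose 12.5-fold (3.65 ± 0.426) and the inhibitor of apoptosis BIRC3 6.92-fold (2.79 ± 0.17). TNF was at least 3.71-fold higher, since it was not above the empty spots in the untreated cells of any array (adjusted p = 5.23e-05). The cell cycle inhibitor CDKN1A rose 4.17-fold (2.06 ± 0.245), the tight junction gene CLDN1 2.99-fold (1.58 ± 0.188) and the mucin gene MUC2 2.57-fold (1.36 ± 0.146). SPRY1, an inhibitor of growth factor signalling, fell 1.7-fold (-0.76 ± 0.122).

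Of 208 genes past the test after S. Typhimurium, 136 were higher and 72 lower. Of 6 neutrophil-attracting chemokines 5 rose and 0 fell with the same members (5 and 0 adjusted over the list alone; adjusted p = 2.45e-17, and 1.56e-06 with an estimated correlation). Of 17 NF-kB genes 10 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 3.94e-12, and 0.000209 with an estimated correlation). Of 25 cytokine genes 10 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 1.69e-08, and 0.000984 with an estimated correlation). Among the 14 AP-1 and immediate early genes 8 rose and 0 fell, 10 and 0 adjusted over the list alone (adjusted p = 2.95e-05, and adjusted p = 0.358 with an estimated correlation). Of 29 type I interferon response genes 11 rose, among them IRF1 with 2.28-fold (1.19 ± 0.134), and 0 fell, 13 and 0 adjusted over the list alone (adjusted p = 0.00106, and adjusted p = 0.415 with an estimated correlation). Of 19 mucins, trefoil factors and tight junction genes 4 rose, CLDN1, CLDN15, MUC2 and TJP1, and CLDN2 fell (5 and 2 adjusted over the list alone), and the list did not pass its test (adjusted p = 0.221). Without replicate 2 the count was 124, and fitted on its 4 arrays alone it was 31, where TNF, CLDN1, CDKN1A and SPRY1 did not pass (adjusted p = 0.127, 0.0757, 0.0896 and 0.146). With median centring 113 genes were higher and 26 lower, and with the slide or session as a block 231 or 230 passed.

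After the S. Enteritidis isolate the same chemokine genes led. CXCL1 rose 8.26-fold (3.05 ± 0.2), n = 4, adjusted p = 2.01e-18, higher on 4 of 4 arrays, and CXCL8 rose 8.11-fold (3.02 ± 0.285). CCL20 rose 3.92-fold (1.97 ± 0.279), CSF2 3.66-fold (1.87 ± 0.209) and NFKBIA 2-fold (1.00 ± 0.114). The signalling inhibitor SOCS3 rose 2.08-fold (1.055 ± 0.176) and ICAM1 1.91-fold (0.93 ± 0.139). JUN, with a log2 change of 0.44, and IRF1, with 0.35, did not pass the test (adjusted p = 0.669 and 0.163); IRF1 passed without replicate 1 (log2 change 0.535, adjusted p = 0.0389) and with a dye effect per slide (0.579, adjusted p = 0.0299). TMX1, which encodes a thioredoxin-like protein, fell 1.37-fold (-0.46 ± 0.095); without the dye column its adjusted p was 0.122.

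Of 38 genes past the test after S. Enteritidis, 30 were higher and 8 lower. Of 6 neutrophil-attracting chemokines 4 rose, CXCL1, CXCL2, CXCL3 and CXCL8, 5 adjusted over the list alone, and 0 fell (adjusted p = 9.07e-24, and 2.54e-08 with an estimated correlation). Of 17 NF-kB genes 5 rose, BIRC3, NFKB2, NFKBIA, NFKBIE and TNFAIP3, 7 adjusted over the list alone, and 0 fell (adjusted p = 0.000122, and 0.0497 with an estimated correlation). Of 40 chemokines 6 rose and 0 fell (adjusted p = 0.000584, and 0.0497 with an estimated correlation). Of 25 cytokine genes 6 rose, 8 adjusted over the list alone, and 0 fell (adjusted p = 0.000584, and adjusted p = 0.0515 with an estimated correlation). The 6 housekeeping genes had a median log2 change of -0.15 (0 fell, 1 adjusted over the list alone; adjusted p = 0.0444, and adjusted p = 0.205 with an estimated correlation). Without replicate 3 the count was 93, and fitted on its 4 arrays alone it was 1; there CXCL1, CCL20, CSF2, NFKBIA, SOCS3 and ICAM1 did not pass, with adjusted p = 0.0829, 0.547, 0.519, 0.178, 0.644 and 0.438. With median centring 24 genes passed, without background correction 65, and with the slide or session as a block 48 or 51.

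LPS tests what 1 bacterial component does without the bacterium. CXCL1 rose 6.82-fold (2.77 ± 0.2), n = 4, adjusted p = 6.84e-17, higher on 4 of 4 arrays, and CCL20 5.95-fold (2.57 ± 0.279). CXCL3 rose 5.69-fold (2.51 ± 0.179), CXCL8 4.01-fold (2.00 ± 0.285) and CXCL6 2.36-fold (1.24 ± 0.168), all neutrophil attractants. BIRC3 rose 2.04-fold (1.03 ± 0.17) and ICAM1 1.77-fold (0.83 ± 0.139). NFKBIA rose 1.42-fold (0.50 ± 0.114), a call lost without replicate 1, 2 or 4 (adjusted p = 0.0667, 0.113 and 0.073). TNFAIP3, with a log2 change of -0.09 ± 0.428, and JUN, with 0.12, did not pass (adjusted p = 0.976 for both).

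All 11 genes past the test after LPS were higher. Of 6 neutrophil-attracting chemokines 5 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 3.96e-33, and 1.51e-10 with an estimated correlation). Of 40 chemokines 7 rose, 8 adjusted over the list alone, and 0 fell (adjusted p = 1.36e-06, and 0.00253 with an estimated correlation). Of 17 NF-kB genes 2 rose, NFKBIA and BIRC3, and 5 adjusted over the list alone (adjusted p = 0.00231, and adjusted p = 0.185 with an estimated correlation). Of 25 cytokine genes 0 passed, 1 adjusted over the list alone (adjusted p = 0.296). The 13 T helper cytokine genes, of which 3 lay above the empty spots, passed the camera test as a group towards lower values with 0 members called (adjusted p = 0.042, and adjusted p = 0.343 with an estimated correlation). With median centring 23 genes passed, with array weights 19, and with the slide or session as a block 12.

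**Figure D2:**
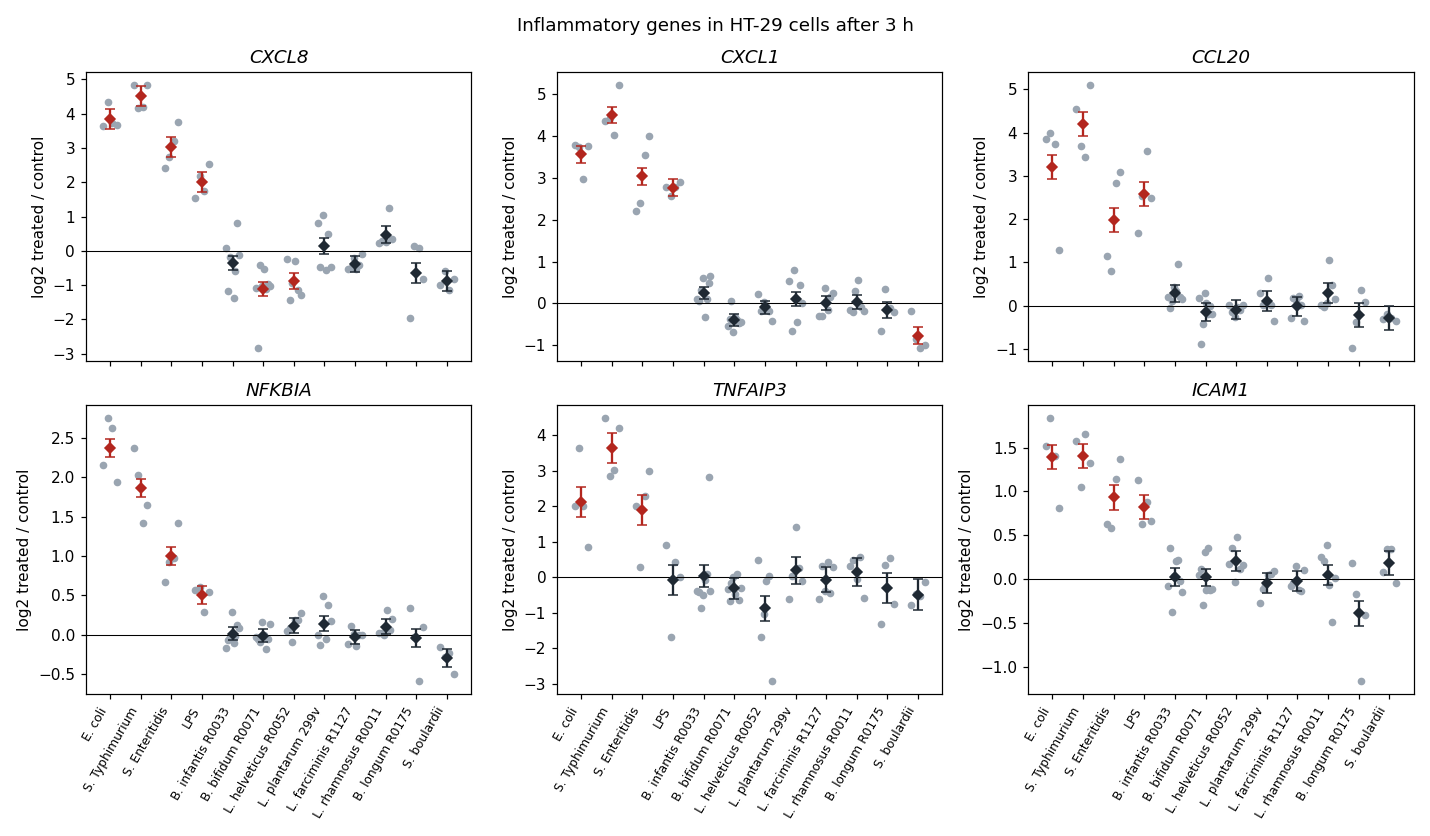
Log2 change of treated over untreated cells for CXCL8, CXCL1, CCL20, NFKBIA, TNFAIP3 and ICAM1 after each of the 12 treatments: grey points are arrays, diamonds the fitted change, bars its SE, and red marks an adjusted p under 0.05. CXCL8 lies at 3.83 after E. coli, 4.51 after S. Typhimurium, 3.02 after S. Enteritidis and 2.00 after LPS.

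Across the 3 Gram-negative bacteria, CXCL8 rose 13.8-fold (3.79 ± 0.165) and CXCL1 13.1-fold (3.71 ± 0.115), both on 12 of 12 arrays. NFKBIA rose 3.36-fold (1.75 ± 0.066), the cytokine gene IL32 2.37-fold (1.24 ± 0.077) and CDKN1A 2.31-fold (1.205 ± 0.141). BMP4, which encodes a bone morphogenetic protein, fell 1.63-fold (-0.71 ± 0.114), lower on 11 of 12 arrays, and ID1 fell 1.57-fold (-0.65 ± 0.083). The LPS receptor TLR4, with a log2 change of 0.02, and its adaptor MYD88, with -0.12, did not pass (adjusted p = 0.873 and 0.465). In this mean 243 genes passed, 149 higher and 94 lower; with median centring 148 were higher and 39 lower, and fitted on these 12 arrays alone 97 passed. Of 17 NF-kB genes 9 rose and 0 fell, 11 and 2 adjusted over the list alone (adjusted p = 2.53e-10, and 0.000773 with an estimated correlation). Of 25 cytokine genes 10 rose and 0 fell (adjusted p = 5.69e-07, and 0.00378 with an estimated correlation), and of 14 AP-1 and immediate early genes 8 rose and 0 fell (adjusted p = 2.38e-05, and adjusted p = 0.287 with an estimated correlation).

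Within imaging session 1, which held arrays of all 4 of these treatments, the log2 change of CXCL8 was 3.67 after E. coli, 4.83 after S. Typhimurium, 3.12 after S. Enteritidis and 1.65 after LPS. Within session 3 it was 3.65, 4.50, 2.72 and 2.36 in the same order, from 1 or 2 arrays each. The mean over the NF-kB genes in session 1 was 0.68, 1.11, 0.44 and 0.18, and in session 3 it was 0.24, 1.01, 0.13 and 0.16.

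The 7 Gram-positive bacteria and the yeast were compared with untreated cells to ask what probiotic strains change. After B. infantis R0033 the antioxidant enzyme gene HMOX1 rose 2.71-fold (1.44 ± 0.104), n = 8, adjusted p = 8.75e-17, higher on 8 of 8 arrays. The growth factor gene FGF19 rose 2.48-fold (1.31 ± 0.196), the kinase gene PIM1 2.46-fold (1.30 ± 0.13) and TLR4 2.07-fold (1.05 ± 0.074). The stress response gene DDIT3 fell 2.5-fold (-1.32 ± 0.132), the immediate early gene EGR1 2.24-fold (-1.165 ± 0.268) and the EGF receptor ligand HBEGF 1.98-fold (-0.99 ± 0.215). The polo-like kinase gene PLK2 fell 1.78-fold (-0.83 ± 0.1), CLDN1 1.71-fold (-0.77 ± 0.133) and the interferon-induced IFIT1 1.69-fold (-0.76 ± 0.16). CXCL8, with a log2 change of -0.36, did not pass (adjusted p = 0.281) except with array weights (log2 change -0.504, adjusted p = 0.0414).

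Of 156 genes past the test after B. infantis, 84 were higher and 72 lower. Of 14 AP-1 and immediate early genes 0 rose and 4 fell, DUSP6, EGR1, GADD45A and GADD45B, or 7 adjusted over the list alone (adjusted p = 0.022, and adjusted p = 0.547 with an estimated correlation). Of 29 interferon response genes 3 fell, IFIT1, IFIT2 and IFI44, and 5 adjusted over the list alone (adjusted p = 0.0433, and adjusted p = 0.547 with an estimated correlation). Of 6 oxidative stress and hypoxia genes 2 rose and 1 fell (adjusted p = 0.124), the last VEGFA with 1.72-fold (-0.78 ± 0.18). Replicate 7 had the largest residual spread of the 64 arrays, and without it 119 genes passed, 50 higher and 69 lower. BMP15 and CACNB4, with log2 changes of 0.96 and 0.95, were lost without it (adjusted p = 0.234 and 0.159), without replicate 1 (0.185 and 0.13), with array weights (0.317 and 0.156) and with printing-block loess (0.0627 and 0.0655). Fitted alone 99 genes passed, and with the slide or session as a block 158 or 190.

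After B. bifidum R0071 CXCL8 fell 2.18-fold (-1.12 ± 0.202), n = 8, adjusted p = 0.000227, lower on 8 of 8 arrays. PLK2 fell 1.71-fold (-0.77 ± 0.1) and CLDN1 1.49-fold (-0.57 ± 0.133). EGR1 fell 2.06-fold (-1.04 ± 0.268) and HBEGF 1.82-fold (-0.86 ± 0.215), calls lost without replicate 2 (adjusted p = 0.0865 and 0.0509). The exchange factor gene SOS1, an activator of RAS, rose 1.82-fold (0.86 ± 0.101), the phosphatase gene PTPRJ 1.82-fold (0.86 ± 0.163) and PIM1 1.49-fold (0.57 ± 0.13). In all 55 genes passed, 27 higher and 28 lower; of 14 AP-1 and immediate early genes 0 rose and 5 fell, DUSP6, EGR1, GADD45A, GADD45B and JUN, also 5 adjusted over the list alone (adjusted p = 0.000195, and adjusted p = 0.609 with an estimated correlation). JUN (adjusted p = 0.0497) was lost without replicate 1, 2, 4, 6, 7 or 8 (adjusted p = 0.0833, 0.245, 0.0546, 0.0543, 0.137 and 0.124). It was also lost without a dye column, with median centring, a dye effect per slide, printing-block loess or background from the empty spots (adjusted p = 0.0737, 0.065, 0.0591, 0.0698 and 0.0606). Of 6 neutrophil-attracting chemokines 1 fell, CXCL8, and 3 adjusted over the list alone (adjusted p = 0.0526). Without replicate 2 the count was 31, with median centring 238, with array weights 108, and with the slide or session as a block 56 or 70.

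After L. helveticus R0052 EGR1 fell 6.95-fold (-2.80 ± 0.311), n = 6, adjusted p = 8.93e-10, lower on 6 of 6 arrays. HBEGF fell 3.5-fold (-1.81 ± 0.249), the AP-1 subunit FOS 3.2-fold (-1.68 ± 0.339), the phosphatase gene DUSP6 2.77-fold (-1.47 ± 0.163) and DDIT3 2.33-fold (-1.22 ± 0.154). The peptide hormone gene ADM rose 2.3-fold (1.20 ± 0.111), HMOX1 1.92-fold (0.94 ± 0.121) and PIM1 1.62-fold (0.70 ± 0.151). CXCL8 fell 1.85-fold (-0.89 ± 0.234), a call lost without replicate 2, 3, 5 or 6 (adjusted p = 0.105, 0.0733, 0.0727 and 0.0829), without a dye column (0.185) and when fitted alone (0.0924). In all 50 genes passed, 16 higher and 34 lower; with median centring 130 passed, 82 higher and 48 lower. Of 14 AP-1 and immediate early genes 0 rose and 4 fell, DUSP6, EGR1, FOS and GADD45A, or 5 adjusted over the list alone (adjusted p = 4.3e-06, and adjusted p = 0.254 with an estimated correlation). Of 6 oxidative stress and hypoxia genes 2 rose, ADM and HMOX1, and 0 fell, 2 and 2 adjusted over the list alone (adjusted p = 0.0255, and adjusted p = 0.0758 with an estimated correlation). Of 12 EGF receptor ligands and growth factors 2 fell, HBEGF and AREG (adjusted p = 0.0255, and adjusted p = 0.254 with an estimated correlation); AREG was lost without replicate 5 (adjusted p = 0.0589), without a dye column (0.127) and when fitted alone (0.062). Without replicate 3 the count was 21, without replicate 5 it was 22 and without replicate 2 it was 32; fitted alone it was 14, where HMOX1 did not pass (adjusted p = 0.0819), and with the slide or session as a block it was 57 or 70.

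**Figure D3:**
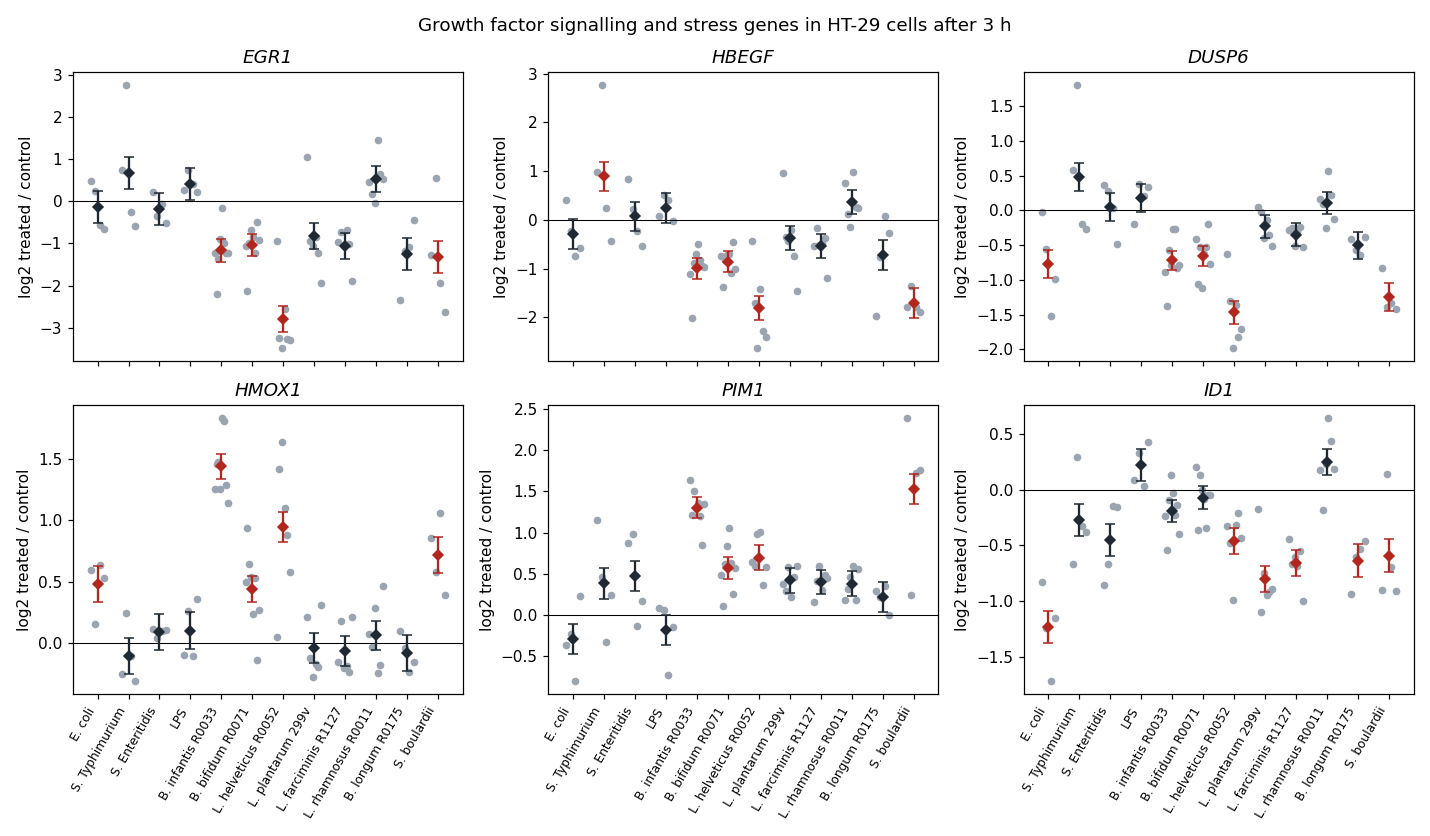
Log2 change of treated over untreated cells for EGR1, HBEGF, DUSP6, HMOX1, PIM1 and ID1 after each of the 12 treatments, marked as grey points for arrays, diamonds for the fitted change, bars for its SE and red for an adjusted p under 0.05. EGR1 lies at -2.80 after L. helveticus R0052 and HMOX1 at 1.44 after B. infantis R0033.

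Sessions 5 and 6 held arrays of B. infantis, B. bifidum and L. helveticus. The log2 change of EGR1 in session 5 was -1.42, -1.22 and -2.09 in that order, and in session 6 it was -0.91, -0.87 and -3.15. HMOX1 was 1.36, 0.65 and 0.73 in session 5 and 1.52, 0.23 and 1.05 in session 6. The mean over the AP-1 and immediate early genes was -0.48, -0.46 and -0.36 in session 5 and -0.20, -0.33 and -0.74 in session 6. B. longum and S. boulardii were each imaged in 1 session of their own.

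After L. plantarum 299v 3 genes fell and 0 rose. ID1 fell 1.74-fold (-0.80 ± 0.118), n = 6, adjusted p = 1.13e-05, lower on 6 of 6 arrays; fitted alone its adjusted p was 0.123. The kinase gene MKNK2 fell 1.4-fold (-0.49 ± 0.103) and was lost without replicate 6 (adjusted p = 0.223), with near-duplicate file names averaged, of which replicate 6 is 1 (0.263), and when fitted alone (0.144). IFNA2, an interferon gene, had a log2 change of -0.45 (adjusted p = 0.0451) but was not above the empty spots in treated cells of any array, so no fold is given; it was lost without replicate 2, 4 or 6 (adjusted p = 0.224, 0.217 and 0.223) and in several alternatives, among them no dye column (0.182) and averaged near-duplicates (0.239). The 14 AP-1 and immediate early genes had a mean log2 change of -0.45, with 0 called and 7 lower adjusted over the list alone (adjusted p = 4.92e-06, and adjusted p = 0.745 with an estimated correlation). This mean was 0.67 on the 1 array of session 7 and -0.68 on the 5 arrays of session 8. The count of 3 became 17 without replicate 1, 9 without replicate 5, 1 without replicate 6, 34 with array weights and 0 when fitted alone, where 156 genes had an unadjusted p under 0.05 in the joint test. With the slide as a block it was 2 and with the session 7; with loess within printing blocks 1 gene was higher and 2 lower, and with scale normalisation 3 and 10.

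After L. farciminis R1127 1 gene passed: ID1 fell 1.58-fold (-0.66 ± 0.118), n = 6, adjusted p = 0.00101. Of the 14 AP-1 and immediate early genes 0 passed and 2 were lower adjusted over the list alone (adjusted p = 1.02e-08, and adjusted p = 0.19 with an estimated correlation). With array weights or fitted alone 5 genes passed. After L. rhamnosus R0011 0 genes passed the limma test and 30 had an unadjusted p under 0.05. JUN had a log2 change of 0.59 ± 0.265 (adjusted p = 1), above 0 on 6 of 6 arrays. The AP-1 and immediate early genes had a median log2 change of 0.34 and a mean of 0.37, with 2 higher adjusted over the list alone (adjusted p = 4.01e-12 towards higher values, and adjusted p = 0.11 with an estimated correlation). With the slide or session as a block the counts were 1 after L. farciminis and 0 after L. rhamnosus.

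After B. longum R0175 6 genes passed. The phosphatase gene DUSP2 fell 2.05-fold (-1.03 ± 0.253), n = 4, SOCS3 1.67-fold (-0.74 ± 0.176), SOCS1 1.54-fold (-0.62 ± 0.154) and ID1 1.55-fold (-0.64 ± 0.144), while YWHAQ rose 1.32-fold (0.405 ± 0.085) and CMTM4 1.27-fold (0.34 ± 0.085). Each of these calls was lost without at least 1 array. Without replicate 1 the adjusted p was 0.316 for DUSP2, 0.217 for SOCS1, 0.0939 for ID1, 0.163 for YWHAQ and 0.408 for CMTM4. Without replicate 2 it was 0.0569 for ID1, without replicate 3 it was 0.225 for SOCS3, and without replicate 4 it was 0.0856 for DUSP2, 0.193 for SOCS3 and 0.267 for SOCS1. Of the 14 AP-1 and immediate early genes 1 fell, DUSP2, and 8 were lower adjusted over the list alone (adjusted p = 5.11e-11, and adjusted p = 0.0554 with an estimated correlation). The 29 interferon response genes had a median log2 change of -0.29 with 0 called, also over the list alone (adjusted p = 1.94e-10, and adjusted p = 0.0554 with an estimated correlation). Neutrophil-attracting chemokines and antigen presentation genes also passed the camera test towards lower values with 0 called (adjusted p = 0.000294 and 0.0212; with an estimated correlation adjusted p = 0.0554 and 0.523). The count was 17 without replicate 1, 13 without replicate 3, 1 with median centring (0 higher and 1 lower), 0 without a dye column, with array weights, with printing-block loess and when fitted alone, and the joint test had 116 genes at an unadjusted p under 0.05.

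After the yeast S. boulardii I-1079 the epithelial transcription factor gene ELF3 rose 3.13-fold (1.65 ± 0.134), n = 4, adjusted p = 2.57e-14, higher on 4 of 4 arrays. FGF19 rose 3.54-fold (1.82 ± 0.277), ADM 2.92-fold (1.55 ± 0.135), PIM1 2.88-fold (1.53 ± 0.184) and the serum response factor gene SRF 2.11-fold (1.08 ± 0.177). HBEGF fell 3.26-fold (-1.70 ± 0.304), DUSP6 2.37-fold (-1.25 ± 0.199), DDIT3 2.35-fold (-1.235 ± 0.187) and the TGF-beta receptor gene TGFBR2 1.45-fold (-0.54 ± 0.076). CLDN1 fell 2.05-fold (-1.03 ± 0.188), while the tight junction genes CLDN2 and CLDN3 rose 1.52-fold (0.60 ± 0.138) and 1.36-fold (0.44 ± 0.09). CXCL8, with a log2 change of -0.885 ± 0.285, did not pass (adjusted p = 0.0511); it passed with the slide or session as a block (adjusted p = 0.0211 and 0.0216), and over all alternatives its adjusted p ranged from 0.000279 (fitted alone) to 0.216 (without replicate 3). EGR1 fell 2.51-fold (-1.33 ± 0.379), lower on 3 of 4 arrays, a call lost without replicate 1, 3 or 4 (adjusted p = 0.0776, 0.172 and 0.306) and when fitted alone (0.0547). In all 80 genes passed, 42 higher and 38 lower. Of 6 oxidative stress and hypoxia genes 2 rose, ADM and HMOX1, and 0 fell, the same counts adjusted over the list alone (adjusted p = 0.00391, and 0.00806 with an estimated correlation). Among the AP-1 and immediate early genes 1 rose, DUSP5, and 2 fell, DUSP6 and EGR1, or 4 and 2 adjusted over the list alone (adjusted p = 0.866). With array weights 146 genes passed, and with the slide or session as a block 116 or 104.

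Across the 3 bifidobacteria, EGR1 fell 2.23-fold (-1.16 ± 0.179), FOS 1.87-fold (-0.90 ± 0.195) and HBEGF 1.81-fold (-0.86 ± 0.143), n = 20. CXCL8 fell 1.63-fold (-0.71 ± 0.134), adjusted p = 0.000141, lower on 16 of 20 arrays. PIM1 rose 1.62-fold (0.70 ± 0.087), HMOX1 1.51-fold (0.60 ± 0.069) and TLR4 1.37-fold (0.46 ± 0.049). The strains differed. By session, HMOX1 was 1.36 and 1.52 after B. infantis, 0.65 and 0.23 after B. bifidum and -0.08 after B. longum, so its rise rests mostly on B. infantis. The TLR4 value includes the larger rise after B. infantis given above. In the bifidobacteria mean 109 genes passed, 44 higher and 65 lower. Of 14 AP-1 and immediate early genes 7 fell, 8 adjusted over the list alone, and 0 rose (adjusted p = 1.93e-10, and adjusted p = 0.142 with an estimated correlation). Of 29 interferon response genes 5 fell, IFI44, IFIT1, IFIT2, IRF7 and IRF9, or 7 adjusted over the list alone, and 0 rose (adjusted p = 8.47e-06, and adjusted p = 0.291 with an estimated correlation). Of 6 neutrophil-attracting chemokines 2 fell, CXCL5 and CXCL8, or 4 adjusted over the list alone (adjusted p = 0.00175, and adjusted p = 0.142 with an estimated correlation). Across the 4 lactobacilli, EGR1 fell 2.05-fold (-1.04 ± 0.155), lower on 18 of 24 arrays, HBEGF 1.5-fold (-0.59 ± 0.124) and ID1 1.33-fold (-0.42 ± 0.059), and PIM1 rose 1.39-fold (0.475 ± 0.075), higher on 24 of 24 arrays. These means do not hold for every strain. By session, EGR1 was -2.09 and -3.15 after L. helveticus, but 0.47, 0.18, -0.05, 1.46 and 0.59 after L. rhamnosus. HBEGF after L. rhamnosus was 0.76, 0.13, -0.15, 0.99 and 0.26. In the lactobacilli mean CXCL8, with a log2 change of -0.16, did not pass (adjusted p = 0.708). There 18 genes passed, 8 higher and 10 lower, with 3 of the AP-1 and immediate early genes lower, EGR1, FOS and DUSP6, and 1 higher and 6 lower adjusted over the list alone (adjusted p = 1.82e-06, and adjusted p = 0.44 with an estimated correlation). With median centring 11 genes were higher and 6 lower, with array weights 39 passed, and fitted on the lactobacilli alone 44.

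**Figure D4:**
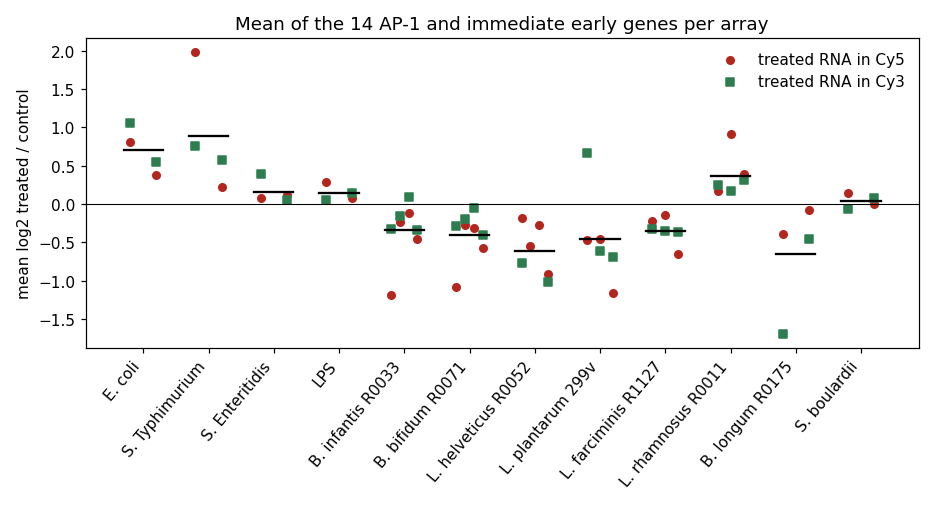
Mean log2 change of the 14 measured AP-1 and immediate early genes on each array, by treatment (circles, treated RNA in Cy5; squares, treated RNA in Cy3; line, mean of the arrays). The mean over arrays is 0.37 after L. rhamnosus R0011 and -0.61 after L. helveticus R0052.

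Gram-negative bacteria were set against the 7 Gram-positive bacteria, a split that goes with the dose and with the imaging session, since no session held both. CXCL8 was higher by 18.1-fold (4.18 ± 0.187) after the Gram-negative bacteria (n = 55 arrays with a value for this gene), CXCL1 by 13.4-fold (3.74 ± 0.131) and CCL20 by 8.56-fold (3.10 ± 0.183). BMP4 was lower by 1.68-fold (-0.74 ± 0.13). The SE cover the spread between arrays and not that between strains. In all 237 genes differed, 139 higher and 98 lower after the Gram-negative bacteria, or 127 and 45 with median centring. Among the 17 NF-kB genes 9 were higher (adjusted p = 2.62e-10, and 0.000786 with an estimated correlation) and of 25 cytokine genes 10 (adjusted p = 2.62e-07, and 0.00313 with an estimated correlation). Of 14 AP-1 and immediate early genes 12 were higher, 13 adjusted over the list alone (adjusted p = 2.62e-10, and adjusted p = 0.0509 with an estimated correlation). Of 29 interferon response genes 7 were higher, 10 adjusted over the list alone (adjusted p = 0.00365, and adjusted p = 0.493 with an estimated correlation).

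LPS was set against the mean of the 3 Gram-negative bacteria to ask how far 1 component matches the whole bacterium. TNFAIP3 was lower after LPS by 6.25-fold (-2.64 ± 0.492), n = 16, adjusted p = 0.000248, CSF2 by 4.99-fold (-2.32 ± 0.242) and CXCL8 by 3.44-fold (-1.78 ± 0.329). ID1 was higher after LPS by 1.83-fold (0.87 ± 0.167). In all 44 genes differed, 8 higher and 36 lower after LPS, or 18 and 22 with median centring. Among NF-kB genes 6 were lower (adjusted p = 2.45e-06, and 0.0187 with an estimated correlation), of 25 cytokine genes 8, 9 adjusted over the list alone (adjusted p = 1.67e-05, and 0.0187 with an estimated correlation), and of 6 neutrophil-attracting chemokines 4, CXCL1, CXCL2, CXCL3 and CXCL8 (adjusted p = 0.000162, and 0.0321 with an estimated correlation). The AP-1 and immediate early genes (2 lower, JUN and JUND) and the mucins, trefoil factors and tight junction genes (0 lower, 2 adjusted over the list alone) also passed towards lower values (adjusted p = 0.0227 and 0.0239; with an estimated correlation adjusted p = 0.676 and 0.0774). The count was 28 without replicate 2 or replicate 4 of LPS and 11 when only these treatments were fitted, and with the slide or session as a block 55 or 58.

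Between the Salmonella serovars, CX3CL1, a chemokine gene, was higher after S. Typhimurium by 4.64-fold (2.21 ± 0.332), n = 8, adjusted p = 3.52e-06, and BIRC3 by 3.61-fold (1.85 ± 0.241). CCL20 was higher by 4.66-fold (2.22 ± 0.395) and CSF1 by 3.69-fold (1.88 ± 0.308), calls lost with a dye effect per slide (adjusted p = 0.162 and 0.13). Of 40 genes that differed 39 were higher and 1 lower after S. Typhimurium; the lower one, PPP2R1A, had a log2 difference of -0.42 ± 0.124 (adjusted p = 0.0317) and was lost without replicate 4 of S. Enteritidis (adjusted p = 0.675) or replicate 1, 2 or 3 of S. Typhimurium (adjusted p = 0.0661, 0.0948 and 0.104) or replicate 3 of S. Enteritidis (adjusted p = 0.0791), and with median centring, array weights, printing-block loess or no dye column (0.875, 0.353, 0.282 and 0.0641). Of 17 NF-kB genes 7 were higher, 8 adjusted over the list alone (adjusted p = 8.26e-13, and 0.000211 with an estimated correlation), and of 6 neutrophil-attracting chemokines 5 (adjusted p = 5.8e-09, and 0.000624 with an estimated correlation). Of 25 cytokine genes 6 were higher (adjusted p = 2.44e-08, and 0.00113 with an estimated correlation). The chemokines as a whole (8 higher), the AP-1 genes (DUSP5 higher, 6 adjusted over the list alone) and the interferon response genes (IRF1 higher) passed with adjusted p = 0.00245, 1.37e-05 and 0.0242, and with an estimated correlation had adjusted p = 0.072, 0.313 and 0.638. Fitted on these 8 arrays alone 3 genes passed and CX3CL1, BIRC3, CCL20 and CSF1 did not (adjusted p = 0.158, 0.0622, 0.347 and 0.517); with the slide or session as a block 40 or 44 passed.

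Between E. coli and the mean of both Salmonella, DUSP1 was higher after E. coli by 3.88-fold (1.96 ± 0.455), n = 12, adjusted p = 0.00225, the growth factor gene KITLG by 2.72-fold (1.445 ± 0.296) and the lipid kinase gene PIK3CB by 2.64-fold (1.40 ± 0.218). The cell cycle inhibitor CDKN2B was lower by 2.95-fold (-1.56 ± 0.329) and SMAD3, which transmits TGF-beta signals, by 2.45-fold (-1.29 ± 0.198). SMAD3 had fallen 1.7-fold (-0.77 ± 0.162) after E. coli, a call lost without replicate 3 (adjusted p = 0.0602), and had risen 1.66-fold (0.73 ± 0.162) after S. Typhimurium. Both calls were lost without a dye column (adjusted p = 0.137 and 0.146) and with each treatment fitted alone (0.15 and 0.169). In all 141 genes differed, 68 higher and 73 lower, or 121 and 37 with median centring, and 0 of the 24 gene lists passed camera. Without replicate 2 or 3 of E. coli the count was 72 or 79; fitted on these 12 arrays alone it was 1, and without a dye column 74. With the slide or session as a block it was 201 or 179.

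Between bifidobacteria and lactobacilli, SOS1 was higher after the bifidobacteria by 1.52-fold (0.61 ± 0.089), n = 44, adjusted p = 5.4e-06, and TLR4 by 1.34-fold (0.42 ± 0.065), while the repressor gene BCL6 was lower by 1.47-fold (-0.56 ± 0.076) and PLK2 by 1.44-fold (-0.52 ± 0.089). In all 13 genes differed, 5 higher and 8 lower. The interferon response genes (IFI44 lower, a call lost without replicate 3 of B. longum, without a dye column or with median centring, adjusted p = 0.066, 0.0674 and 0.0703), the AP-1 genes (GADD45B lower, 3 adjusted over the list alone) and the neutrophil-attracting chemokines (0 lower) passed camera with adjusted p = 8.14e-08, 0.0021 and 0.00732, and with an estimated correlation had adjusted p = 0.278, 0.641 and 0.278. Without replicate 1 of B. longum 20 genes differed, with array weights 34, fitted on the 7 strains alone 27, and with the slide or session as a block 11 or 19.

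Between S. boulardii and the mean of the 7 Gram-positive bacteria, ELF3 was higher after the yeast by 3.18-fold (1.67 ± 0.141), n = 48, adjusted p = 8.96e-14, FOS by 3.74-fold (1.90 ± 0.433), FGF19 by 2.95-fold (1.56 ± 0.29) and ADM by 2.53-fold (1.34 ± 0.142), and IFRD1, an interferon-related regulator, was lower by 1.84-fold (-0.88 ± 0.128). In all 46 genes differed, 25 higher and 21 lower. Of 6 oxidative stress and hypoxia genes 1 was higher, ADM (adjusted p = 0.011, and 0.0188 with an estimated correlation), and of 14 AP-1 and immediate early genes 3 were higher, FOS, JUN and DUSP5, and DUSP6 lower (adjusted p = 0.0214, and adjusted p = 0.48 with an estimated correlation). Without replicate 3, 4 or 2 of S. boulardii the count was 23, 27 or 28, and with the slide or session as a block 58 or 55; S. boulardii shared no session with the bacteria.

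Over the 12 treatments and 24 gene lists, 34 of 288 tests passed with the preset correlation and 12 with an estimated one. Leukocyte markers (22 measured) and antimicrobial defence genes (10 measured) had 0 members called after any of the 12 treatments by limma, and neither list passed camera. Housekeeping genes also had 0 members called after any single treatment, on the brightest probe of each gene, and passed camera after 1. After E. coli 1 of the 3 probes of B2M and 1 of the 2 of HPRT1 was called, neither of them the brightest. In the Gram-negative mean 2 of them were lower, GAPDH with a log2 change of -0.18 (adjusted p = 0.00725) and RPLP0 with -0.173 (adjusted p = 0.0328), both lost with median centring (adjusted p = 0.66 and 0.756) or array weights (0.295 and 0.271). RPLP0 was also lost without replicate 1 or 2 of E. coli (0.0898 and 0.177), 3 or 4 of S. Typhimurium (0.115 and 0.122) or 1 or 4 of S. Enteritidis (0.0794 and 0.141). Counted as pairs of gene and treatment, TLR and IL-1 receptor signalling had 13 higher and 12 lower, the MAP kinase cascade 18 and 14, JAK-STAT and SOCS genes 8 and 10, TNF receptors and death receptors 10 and 6, BCL2 family genes and caspases 1 and 6, and NOD-like receptors 1 and 4. Mucins, trefoil factors and tight junction genes had 13 higher and 6 lower, adhesion molecules 5 and 1, heat shock genes 5 and 1, TGF-beta and SMAD genes 7 and 19, cell cycle genes 3 and 4, T helper cytokines 3 and 1, EGF receptor ligands 5 and 5, and antigen presentation genes 3 and 0.

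Similarity between responses was taken as the correlation of log2 changes across genes, which are not independent replicates, so no p-value is given. Pearson r was highest between the Salmonella serovars (r = 0.81, Spearman rho = 0.57, covariance 0.109), where 28 genes rose after both and 7 fell after both, against 3.02 and 0.426 by chance overlap of lists of these sizes. With signs of arrays turned at random 100 times, the middle 95% of this r lay between -0.65 and 0.59. Ranges with signs turned below are the same middle 95%, so single draws lay outside them. E. coli and S. Typhimurium had r = 0.56, rho = 0.08 and a larger covariance of 0.115 (range of r with signs turned -0.5 to 0.45), with 43 genes higher and 6 lower after both, against 9.66 and 3.57 by chance, and 7 called in opposite directions. LPS had r = 0.53 with E. coli, 0.53 with S. Typhimurium and 0.47 with S. Enteritidis. B. bifidum and L. helveticus had r = 0.60 and rho = 0.53 (range with signs turned -0.44 to 0.51). S. boulardii, which shared no slide with them, had r = 0.41 with B. infantis, 0.41 with B. bifidum and 0.42 with L. helveticus. With B. infantis 15 genes were higher and 21 lower after both, against 2.61 and 2.02 by chance. B. longum had r = -0.42 with S. Typhimurium, inside the range with signs turned (-0.43 to 0.39), and -0.38 with E. coli (range -0.35 to 0.27). The labels do not say whether arrays shared untreated RNA, which would raise these correlations.

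**Figure D5:**
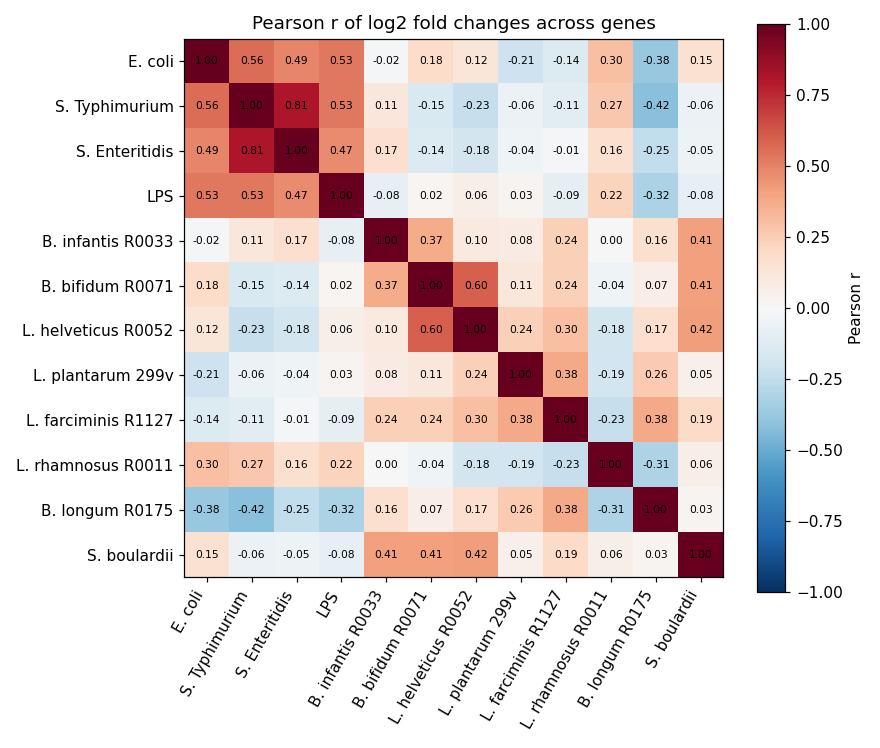
Pearson correlation across genes between the log2 changes of each pair of the 12 treatments, shown as colour with the value printed. The highest is 0.81, between the Salmonella serovars.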

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

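The tests of a response to the strain, of handling between campaigns, of the noise of a single array, of the signal near the empty spots, of slide position, of imaging sessions and of a single array below were chosen after the results were seen; the tests of the dye effect, of variation between dishes and of regroupings were not.

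Single arrays stood apart from the others of their treatment in log2 change. After E. coli, CXCL8 was 4.33 on replicate 2 (others 3.63 to 3.72), CXCL1 2.98 on replicate 3 (3.75 to 3.79), CCL20 1.28 on replicate 4 (3.74 to 3.98), DUSP1 3.58 on replicate 3 (2.49 to 2.59) and TICAM1 0.09 on replicate 4 (0.84 to 0.98). After S. Typhimurium, replicate 2 had CSF1 at 2.65 (3.48 to 3.57) and JUN at 2.94 (1.07 to 1.15). After B. infantis, HBEGF was -2.02 on replicate 2 (-1.11 to -0.49). After B. bifidum, replicate 2 had CXCL8 at -2.83 (-1.11 to -0.41) and EGR1 at -2.14 (-1.22 to -0.49). After L. helveticus, replicate 1 had EGR1 at -0.93 (-3.48 to -2.56), BIRC3 at -0.20 (-0.76 to -0.66) and CLDN1 at 0 (-0.79 to -0.61), and replicate 3 had ID1 at -0.99 (-0.48 to -0.21). CXCL8 was 1.25 on replicate 4 of L. rhamnosus (0.23 to 0.33) and CMTM4 0.83 on replicate 1 of B. longum (0.15 to 0.20). After S. boulardii, replicate 2 had HBEGF at -1.35 (-1.88 to -1.79) and TGFBR2 at -0.39 (-0.60 to -0.57), and replicate 1 had DUSP6 at -0.84 (-1.42 to -1.34). The residual SD over genes was 0.653 on replicate 7 of B. infantis (0.218 to 0.366) and 0.44 on replicate 2 of B. bifidum (0.207 to 0.29). Of 211 sets of arrays examined 21 had such an array, against 10.6 by chance, which gives about 1 in 20.

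Treatments differed by direct test in 237 genes between Gram-negative and Gram-positive bacteria, 44 between LPS and the Gram-negative bacteria, 40 between the Salmonella serovars, 141 between E. coli and Salmonella, 13 between bifidobacteria and lactobacilli, and 46 between S. boulardii and the Gram-positive bacteria. None of the 228 unnamed spots lay above the empty ones (0 spots).

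Arrays were regrouped at random, and the share of groupings with a count as large as the real one was taken, the real one included. Shares were not adjusted over the comparisons, and arrays of 1 slide or session may not be exchangeable. The share was under 0.05 for B. infantis (1 of 100 groupings, real count 157, highest other 97), B. bifidum (1 of 100, 59 and 24) and L. helveticus (1 of 32, 52 and 34). It was also under 0.05 for the means of the Gram-negative bacteria (1 of 100, 247 and 181), bifidobacteria (1 of 100, 112 and 78) and lactobacilli (1 of 100, 18 and 6). For L. farciminis 1 gene stood against 0 in every other grouping (1 of 32), the smallest share possible there, so it decides little. Among contrasts the share was under 0.05 for Gram-negative against Gram-positive bacteria (1 of 100, 237 and 3), bifidobacteria against lactobacilli (1 of 100, 15 and 4) and S. boulardii against Gram-positive bacteria (1 of 100, 47 and 41). It was also under 0.05 for LPS against Gram-negative bacteria (2 of 100, 56 and 88) and E. coli against Salmonella (3 of 100, 148 and 180). In both of these a regrouping gave more genes than the real grouping. The share was over 0.05 for L. plantarum (7 of 32, 3 and 20), L. rhamnosus (32 of 32, 0 and 0) and S. Typhimurium against S. Enteritidis (4 of 35, 40 and 105). With 4 arrays only 8 groupings exist, too few for a share under 0.05: the real and highest other counts were 173 and 149 for E. coli (1 of 8), 211 and 135 for S. Typhimurium (1 of 8), 40 and 76 for S. Enteritidis (3 of 8), 11 and 3 for LPS (1 of 8), 6 and 95 for B. longum (5 of 8) and 83 and 10 for S. boulardii (1 of 8). The largest other groupings of E. coli and S. Typhimurium followed the imaging session. Both had sessions with a single array, and turning only such an array also counts as following the session, so no session structure is shown. For L. rhamnosus every other grouping gave 0 genes, so none of them stands out. With the session as a block the counts were 191, 230 and 0 for E. coli, S. Typhimurium and L. rhamnosus. The grouping of L. plantarum with 20 genes followed the dye orientation. With a dye effect per slide the count was 7. No slide of L. plantarum held both orientations, so that setting gave these slides no term of their own. It therefore cannot test a dye structure there. The 95 genes of 1 regrouping of B. longum, and the 20 of L. plantarum, are several times the real counts, which points to a structure of the samples. For B. longum it followed neither session nor dye and was not tested further.

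The mean log2 change of AP-1 and immediate early genes was below 0 after 6 of the 7 Gram-positive strains and above 0 after L. rhamnosus. Over all 12 treatments the list passed camera after 9 with the preset correlation but after 0 with an estimated one, and after L. rhamnosus, L. plantarum and L. farciminis 0 members passed. A dye effect of these genes is argued against, since its mean over the list was 0.01 of the median size of the strain means, 0.40. A permutation of strain labels over the arrays gave p = 0.0032 for the spread of strain means (2-sided, 1e+05 permutations). The pattern was read from these same arrays in 1 of 24 lists, and p makes no allowance for that choice. The permutation also takes arrays of different sessions as exchangeable. Chance variation between dishes therefore stays open. Handling that differed between campaigns cannot be told apart from the strain, since most strains lay in sessions of their own and the permutation within sessions 5 and 6, which hold 3 of the strains, gave p = 0.33. A response to the strain may account for the pattern and also stays open: for 5 of the 7 strains all arrays lay on 1 side of 0.

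Of the 156 genes past the test after B. infantis, 51 were lost without replicate 7 (38 of them higher), and 105 were kept. Noise of that 1 array stays open. The median log2 change of the lost genes towards their called direction was 1.23 on replicate 7 and 0.26 on the other 7 arrays, a ratio of 4.77, but the choice of genes lost without replicate 7 fixes this difference, so it decides nothing. Signal near the empty spots stays open, since a share of 0.86 of the lost genes lay above them. A response to the strain stays open for these genes too: a share of 0.51 kept their direction on 6 or more of the other 7 arrays.

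Of the 141 genes that differed between E. coli and Salmonella, a share of 0.87 (123 genes) kept the call with loess within printing blocks, which argues against position on the slide as the whole cause. A difference between imaging sessions stays open. Within session 1 and within session 3, where it drops out, a share of 0.93 (131 genes) had 1 direction. These genes were chosen mostly from arrays of these sessions, which raises that share by an unknown amount. With the session as a block 138 genes kept the call, but that block acts on the ratio of Cy5 over Cy3. A session shift of treated over untreated cells changes sign with the dye, so the block misses it. A share of 0.3 (43 genes) kept the call with each of the 12 arrays left out, so dependence on a single array may hold for the rest and stays open. The biological difference between the species was not tested apart from these.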

How the results depend on the processing

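The alternatives of printing-block loess, scale normalisation, the session block, background from the empty spots, only genes above the empty spots and leaving out the noisiest array were tests chosen after the data were seen. Of the counts of called genes, the number of list tests and the similarities under the alternatives, 609 values stayed within 1.5 times the reported one (or within its spread) and 100 did not. Among genes and gene lists 7962 values kept direction and side of the threshold, 29 gained the call and all others lost it except 1 that reversed: the cytokine list after S. Enteritidis among probes above the median intensity (adjusted p = 0.659), where fewer genes are tested. Of 259 called gene values, 169 were kept when each treatment was fitted alone and 55 were lost without at least 1 array; 0 reversed in any setting. Values past the threshold in neither setting had no direction compared. Unless stated, the cause was not tested.

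Fitting each treatment alone leaves fewer arrays to estimate the spread and no longer shares 1 spread per probe over all treatments. It gave 28 genes for E. coli, 31 for S. Typhimurium, 1 for S. Enteritidis, 99 for B. infantis, 14 for L. helveticus, 0 for L. plantarum, 5 for L. farciminis, 1 for L. rhamnosus, 0 for B. longum, 97 for the Gram-negative mean, 44 for the lactobacilli mean, 11 for LPS against Gram-negative bacteria, 3 between the Salmonella serovars, 1 for E. coli against Salmonella and 27 for bifidobacteria against lactobacilli. Fewer arrays cannot be the whole account, since some counts rose, from 1 for L. farciminis, 18 for the lactobacilli mean and 13 for bifidobacteria against lactobacilli. Array weights lay between 0.43 and 1.61 for E. coli and between 1.61 and 2.32 for L. farciminis, so 1 shared spread does not describe each treatment equally well. Median centring gave 24 for S. Enteritidis, 23 for LPS, 238 for B. bifidum, 130 for L. helveticus, 2 for L. rhamnosus, 1 for B. longum and 8 for bifidobacteria against lactobacilli. No background correction gave 65 for S. Enteritidis and 11 for L. plantarum, and plain subtraction 64 and 11. A dye effect per slide gave 24 for S. Enteritidis, 17 for LPS, 7 for L. plantarum, 2.1e+02 (rounded) for E. coli against Salmonella and 20 for bifidobacteria against lactobacilli. No dye column gave 0 for B. longum, 74 for E. coli against Salmonella, 6 for bifidobacteria against lactobacilli and 27 for S. boulardii against Gram-positive bacteria. Array weights gave 19 for LPS, 108 for B. bifidum, 34 for L. plantarum, 5 for L. farciminis, 6 for L. rhamnosus, 0 for B. longum, 146 for S. boulardii, 39 for the lactobacilli mean, 34 for bifidobacteria against lactobacilli and 72 for S. boulardii against Gram-positive bacteria.

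The threshold of the design text, unadjusted, gave 72 for S. Enteritidis, 45 for LPS, 92 for L. helveticus, 31 for L. plantarum, 8 for L. farciminis, 10 for L. rhamnosus, 49 for B. longum, 93 for the Gram-negative mean, 25 for the bifidobacteria mean, 8 for the lactobacilli mean, 103 for Gram-negative against Gram-positive bacteria, 93 for LPS against Gram-negative bacteria, 93 between the Salmonella serovars, 231 for E. coli against Salmonella and 20 for bifidobacteria against lactobacilli. Asking also for 1.3-fold, which by construction removes small changes, gave 90 for B. infantis, 27 for B. bifidum, 89, 25 and 7 for the Gram-negative, bifidobacteria and lactobacilli means, 97 for Gram-negative against Gram-positive bacteria and 7 for bifidobacteria against lactobacilli. For L. plantarum probes above the median intensity gave 6, averaged near-duplicates 1, the session block 7 and scaling 13. Averaged near-duplicates gave 25 for S. boulardii against Gram-positive bacteria. Scaling gave 3 for L. farciminis and 6 for L. rhamnosus, printing-block loess 1 for L. rhamnosus and 0 for B. longum, and background from the empty spots 1 and 3. With an estimated correlation 12 of 288 list tests passed in place of 34.

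Leaving out 1 array, which leaves fewer arrays, gave 101 to 224 genes for E. coli, 124 to 231 for S. Typhimurium, 26 to 93 for S. Enteritidis, 9 to 13 for LPS, 119 to 168 for B. infantis, 31 to 61 for B. bifidum, 21 to 65 for L. helveticus, 1 to 17 for L. plantarum, 1 for L. farciminis, 0 for L. rhamnosus, 5 to 17 for B. longum and 57 to 65 for S. boulardii. It gave 185 to 266, 99 to 118 and 15 to 22 for the Gram-negative, bifidobacteria and lactobacilli means, 195 to 254 for Gram-negative against Gram-positive bacteria, 28 to 62 for LPS against Gram-negative bacteria, 27 to 51 between the Salmonella serovars, 72 to 191 for E. coli against Salmonella, 10 to 20 for bifidobacteria against lactobacilli and 23 to 52 for S. boulardii against Gram-positive bacteria.

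Aquantile between arrays leaves log ratios unchanged by construction. The series table of the authors, with 1 value per treatment, allowed no test and gave no count of called genes; for the median Pearson r between treatments it gave 0.07 in place of 0.074, and restricting to genes past the threshold in either treatment gave 0.139. No paired analysis between treatments was run, since the labels give no replicate numbers. Numbers in the scanner headers were not fitted as a block, and arrays of different treatments with the same session and number had a mean residual correlation of 0.047. Treated and untreated RNA are already compared within each array. Signal over background limits what could be seen: 1108 of 1352 genes lay above the empty spots on a share of at least 0.5 of the arrays.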

Other observations

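No test in this part beyond those of the report was planned for these genes; their grouping was chosen after the values were seen.

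Genes of BMP and TGF-beta signalling changed after several treatments. ID1, a target of BMP signalling, fell after E. coli, L. plantarum, L. farciminis and, in a call lost without replicate 1 or 2, B. longum, as given above, and also 1.37-fold (-0.46 ± 0.118) after L. helveticus, n = 6, and 1.51-fold (-0.59 ± 0.144) after S. boulardii, n = 4. The call after L. helveticus was lost without replicate 3 (adjusted p = 0.178) and with median centring (log2 change -0.252, adjusted p = 0.159), and that after S. boulardii without replicate 1 or 4 (adjusted p = 0.0974 and 0.0985). BMP2 rose 2.14-fold (1.095 ± 0.131) after E. coli and 2.11-fold (1.075 ± 0.131) after S. Typhimurium (fitted alone, adjusted p = 0.0543), n = 4 each, and fell 1.27-fold (-0.34 ± 0.092) after B. infantis, n = 8. TGFBR2 fell 1.27-fold (-0.34 ± 0.054) after B. infantis. No gene list of this signalling passed camera after any of the 12 treatments (0 of 12).

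The list of mucins, trefoil factors and tight junction genes passed camera after 0 of 12 treatments; single members were called. After E. coli the tight junction gene CLDN2 rose 1.43-fold (0.52 ± 0.138), n = 4, a call lost without replicate 1 or 3 (adjusted p = 0.102 and 0.0557) and when fitted alone (0.117). MUC2, which encodes the main secreted gut mucin, rose 1.55-fold (0.63 ± 0.103) after B. infantis, n = 8. CLDN1 fell 1.53-fold (-0.61 ± 0.154) after L. helveticus, n = 6, a call lost without replicate 3 or 5 (adjusted p = 0.0733 and 0.0643). In the MAP kinase cascade MAP3K8 rose 1.7-fold (0.77 ± 0.149) after E. coli and 2.06-fold (1.045 ± 0.149) after S. Typhimurium, calls lost when each treatment was fitted alone (adjusted p = 0.124 and 0.0905). After B. infantis the death receptor gene TNFRSF21 rose 1.31-fold (0.39 ± 0.101) and the chaperone gene HSPA1B 1.49-fold (0.58 ± 0.138).

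The receptor gene TLR2 was called after none of the 12 treatments (0 by limma). TLR3 after B. infantis had a log2 change of -0.38 (adjusted p = 0.047). The correlation of residuals between arrays of 1 slide was 0.211, between arrays of 1 imaging session 0.113, and between arrays of different treatments on 1 slide 0.056 over 17 pairs. Pairs of arrays with nearly equal file names had correlations of 0.42 and 0.17 in L. plantarum (range in the group -0.18 to 0.54) and 0.29 in S. boulardii (0.26 to 0.52).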
